A study of Homo sapiens with 12 samples.

How the data were processed

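Poly(A) RNA of HuCCT-1 and KKU-213A cells, untreated or treated with 100 nM RMC-7977 for 24 h, had been sequenced as strand-specific paired-end libraries on a NextSeq2000. There were 12 libraries in 4 groups of 3, grouped by the line and treatment that the labels give. Each deposited file holds raw counts of fragments per gene for 1 library. Per the file headers, the authors counted with featureCounts 1.6.0 over the exons of each gene, for pairs on the reverse strand, with the GENCODE 45 annotation and without reads that map to several positions or overlap several genes. The authors' processing notes list GRCh38, FastQC 0.11.8 and STAR 2.7.9a, and edgeR and limma without a version. The sources used here do not state whether adapters were trimmed. The file headers also hold a folder name that mentions xenografts and human FASTQ files, while the labels describe cultured cell lines. The labels were followed, and it is not known whether reads of a host were removed before counting, which leaves the values of stromal and endothelial genes such as VWF and COL1A1 uncertain.

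The files hold 63187 genes. Coordinates were taken from the count files. Symbols came from a table of Ensembl IDs, in which 62030 IDs matched with their version and 636 after the version was removed, and 521 had no symbol. All values were whole numbers. Totals were 13.9, 17.8 and 20.1 M (mega) fragments in untreated HuCCT-1, 20.9, 19.4 and 19.5 M in treated HuCCT-1, 18.6, 17.6 and 17.2 M in untreated KKU-213A, and 19.4, 17.2 and 16.3 M in treated KKU-213A. A count of 3 reads over a group, the floor used for groups at 0, equals 0.0567, 0.0487, 0.055 and 0.061 CPM in these groups. The common biological coefficient of variation was 5.2%. Between libraries of a group the chi-square per gene was 1.99 to 9.27, so none repeats another.

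Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with the 4 groups, which left 16321, and libraries were scaled by the trimmed mean of M values (TMM; factors 1.011 to 1.039, and 0.92 to 0.935 in treated KKU-213A). A quasi-likelihood model with a mean per group was fitted to all 12 libraries, with 8 residual degrees of freedom. The 4 contrasts were treated minus untreated in each line, the difference between these 2 responses (KKU-213A minus HuCCT-1), and untreated KKU-213A minus untreated HuCCT-1. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. CPM are on the TMM scale, with the SD over 3 libraries, and a prior count of 2 was used for log2 CPM. Genes called in the same direction in both lines were counted against the number expected of independent lists, with Fisher's exact test. Principal components were computed from log2 CPM.

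A set of 28 gene lists with 514 genes was written from general knowledge and tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, beside the numbers of members higher, lower and not past the threshold. Lists with fewer than 3 tested members got no test, which left 27. The hepatocyte list had 2 tested members.

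The named genes followed a rule. It took 12 fixed genes, KRAS, NRAS, HRAS, PPIA, DUSP6, SPRY4, ETV4, ETV5, MYC, CCND1, CDKN1B and MKI67. It added the 6 highest and 6 lowest genes of each response by log2 fold change, past the threshold, with a mean log2 CPM of at least 3, all treated libraries on one side of all control libraries and a symbol that is not a clone or locus name. It further added the 2 members with the smallest adjusted p of each list past the threshold in a response. For the difference and for the untreated lines it took the 5 highest and 5 lowest genes past the threshold with a mean log2 CPM of at least 3. Other genes named in the text were chosen after their values were seen. The groups, tests, lists, rule and alternatives were fixed before the data were examined.

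The alternatives were DESeq2's size factors in edgeR, no filter on low counts, a stricter filter of at least 1 CPM in 3 libraries, each line fitted by itself, the replicate number within a line as a block, DESeq2's Wald test, limma-voom, camera with an estimated correlation, fry, and leaving out each of the 12 libraries. Where a library was left out, the 2 remaining ones shared the spread of all groups. Libraries were also regrouped in other splits to count how often as many genes or lists passed.

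The tests were tested on simulated data, in which 50 genes per fold were changed among 15609 to 15648 genes. The share of changed genes recovered at 1.25-, 1.5-, 2- and 4-fold was 38%, 72%, 86% and 96% for HuCCT-1 and 46%, 60%, 78% and 92% for KKU-213A. It was 24%, 54%, 66% and 80% for the difference and 42%, 56%, 72% and 90% for the untreated lines, with 5 to 12 calls among unchanged genes. Far fewer genes were changed there than were called in the data, where 43.6% to 77.9% of genes passed. These rates therefore need not hold for the data. No library was left out. Reads were not aligned again, and genes without a symbol were tested but not named.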

Results

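Gene expression was measured by strand-specific sequencing of poly(A) RNA in HuCCT-1 and KKU-213A, 2 human cell lines from cholangiocarcinoma, a cancer of the bile ducts. The labels list KRAS and TP53 in the genotype of both lines. Cells were left untreated or received 100 nM RMC-7977 for 24 h. RMC-7977 inhibits the active, GTP-bound form of several RAS proteins, which it binds in a complex with cyclophilin A, the product of PPIA. Per the labels, the aim was to find which pathways change with the treatment. There were 4 groups of 3 libraries, 12 libraries in all. The total per library was 13.9 to 20.1 M (mega) fragments in untreated HuCCT-1, 19.4 to 20.9 M in treated HuCCT-1, 17.2 to 18.6 M in untreated KKU-213A and 16.3 to 19.4 M in treated KKU-213A. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The first principal component, with 72.4% of the variance, separated the lines, and the second, with 19.5%, separated treated from untreated libraries.

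In treated HuCCT-1, transcripts that ERK signalling induces, transcripts of DNA replication and mitosis, and transcripts of ribosome biogenesis fell. Transcripts of epithelial junctions, cholangiocytes, interferon responses, MHC class I antigen presentation and lysosomes rose. DUSP6, a phosphatase that inactivates ERK and is itself induced by it, fell from 55.9 ± 1.06 to 0.635 ± 0.178 CPM (edgeR's counts scaled to library size; mean ± SD, n = 3 per group), which is 87.4-fold. MYC fell 11.5-fold, from 190 ± 6.51 to 16.5 ± 0.971 CPM, and CCND1, which encodes cyclin D1, fell 17.0-fold, from 881 ± 22.5 to 51.8 ± 2.63 CPM. MKI67, the gene of the proliferation marker Ki-67, fell 4.60-fold, from 614 ± 20.8 to 133 ± 10.7 CPM. In all, 5709 of the 16321 genes tested were higher and 5575 lower in treated cells at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and 2531 and 1932 of these changed at least 2-fold.

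The fixed genes of the pathway lay, on GRCh38, on chromosome 12 from 89347235 to 89352501 for DUSP6 (ENSG00000139318.8), on chromosome 5 from 142310427 to 142326455 for SPRY4 (ENSG00000187678.10), on chromosome 17 from 43527844 to 43579620 for ETV4 (ENSG00000175832.13) and on chromosome 3 from 186046314 to 186110318 for ETV5 (ENSG00000244405.8). MYC (ENSG00000136997.22) spans 127735434 to 127742951 on chromosome 8. CCND1 (ENSG00000110092.4) spans 69641156 to 69654474 on chromosome 11 and KRAS (ENSG00000133703.14) spans 25205246 to 25250936 on chromosome 12. The values are counts over all annotated exons of each gene, untranslated regions included. In HuCCT-1 the log2 fold changes were -6.45 (SE 0.13) for DUSP6, -5.68 (SE 0.12) for SPRY4, a further feedback inhibitor of the pathway, -5.41 (SE 0.10) for ETV4 and -6.28 (SE 0.13) for ETV5, both transcription factors induced by ERK. Their adjusted p-values ranged from 6.97e-23 to 1.97e-22 (edgeR). KRAS rose 1.89-fold, from 62.3 ± 2.73 to 118 ± 13.6 CPM (adjusted p = 6.52e-10). HRAS and PPIA fell by 0.37 and 0.33 on the log2 scale, and CDKN1B, which encodes the CDK inhibitor p27, rose by 0.47. NRAS was at 204 ± 14.0 CPM in untreated and 213 ± 28.3 CPM in treated cells, a difference within the spread (log2 fold change 0.06, adjusted p = 0.456), and its sign turned to -0.05 without treated library 2.

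**Figure D1:**
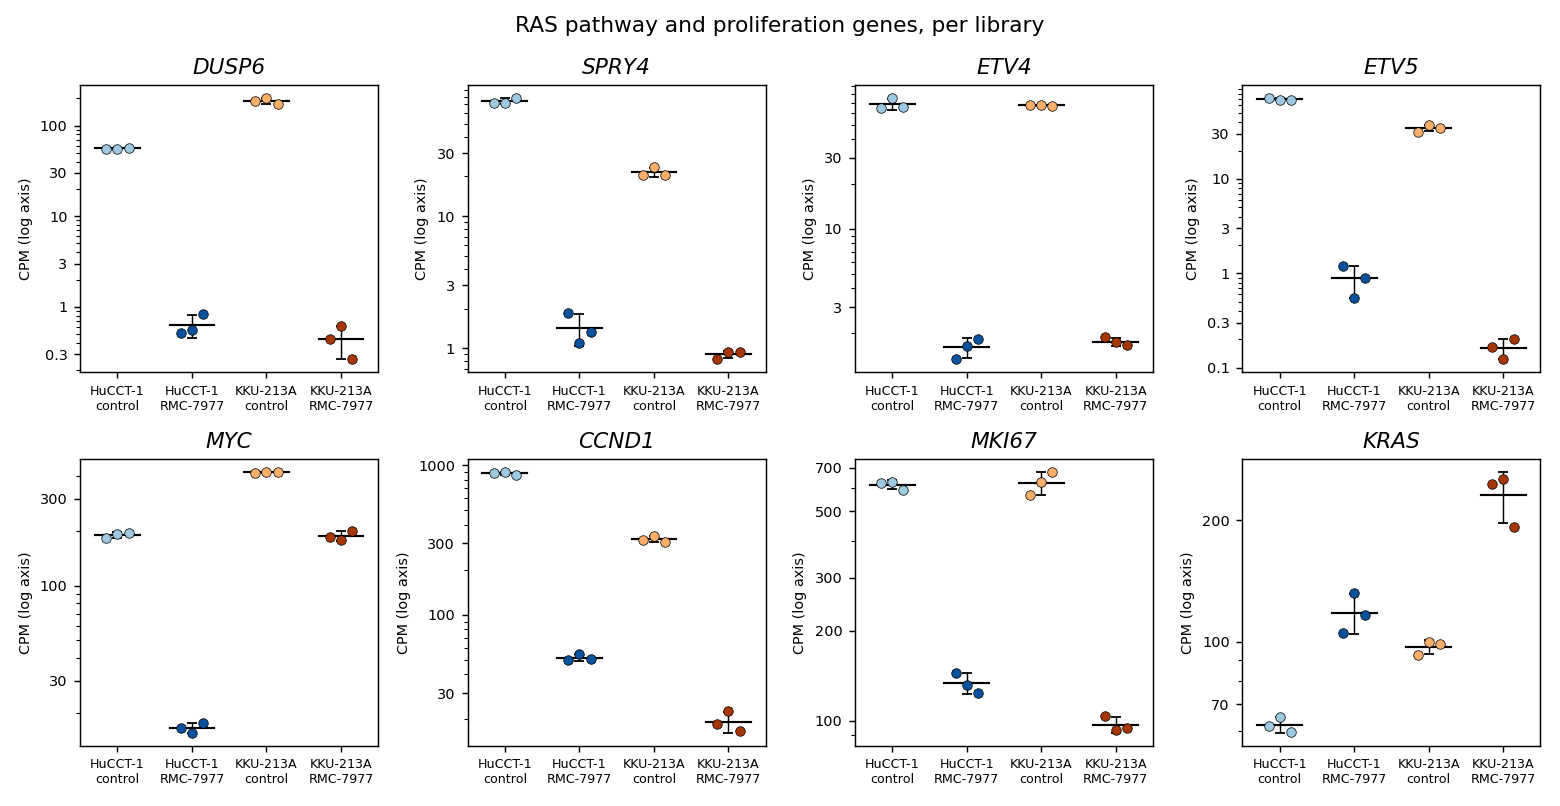
Level of 8 genes in each of the 12 libraries, in CPM on log axes, for untreated and treated HuCCT-1 and KKU-213A. Points are libraries, long lines are group means and error bars are SDs (n = 3); in both lines DUSP6, SPRY4, ETV4, ETV5, MYC, CCND1 and MKI67 are lower and KRAS is higher in treated cells.

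Of the 11 tested ERK feedback regulators, 9 fell, 1 rose and 1 did not pass the test in HuCCT-1 (median log2 fold change -2.20; camera adjusted p = 1.08e-11). Of 18 ERK-induced transcription factors and other ERK targets, 14 fell and 3 rose (median -2.45; camera adjusted p = 3.89e-19). With an estimated correlation, camera's adjusted p was 0.00478 for each of these lists. The ERK targets that rose were JUN (0.37), JUNB (1.32) and EPHA4 (0.83). Here and in the other lists, members given with a log2 value in brackets or no value at all were chosen after their values were seen. FOSL1, which encodes the AP-1 subunit FRA-1, fell 18.1-fold. All 26 members of the G1/S and DNA replication list fell (median -2.30), among them the helicase subunit gene MCM2 (6.08-fold lower) and the flap endonuclease gene FEN1 (5.65-fold lower). All 23 G2/M and mitosis genes fell as well (median -2.15), with CCNB1, which encodes cyclin B1, 5.34-fold and CDC20, an activator of the anaphase-promoting complex, 5.82-fold lower. The camera adjusted p-values of these lists were 6.06e-48 and 5.08e-44 at the preset correlation, and 6.22e-06 and 0.00223 with an estimated correlation. All 25 ribosome biogenesis and MYC-linked growth genes fell (median -1.64; camera adjusted p = 3.57e-31, and 0.00478 with an estimated correlation). ODC1, the polyamine synthesis enzyme, fell by 4.69-fold and NOP56 by 4.63-fold. Among 19 CDK inhibitors and cell cycle exit genes, 12 rose and 4 fell (median 0.47; camera adjusted p = 0.00423, but adjusted p = 0.093 with an estimated correlation). CDKN2B, the gene of the CDK4 and CDK6 inhibitor p15, rose 11.3-fold and CCNG2, which encodes cyclin G2, 4.15-fold.

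Among the lists that rose in HuCCT-1, 9 of 14 tested cholangiocyte genes were higher and 2 lower (median 1.88, or 1.16 with genes at 0 in a group set at their bound; camera adjusted p = 1.01e-05). The surface glycoprotein gene CD24 rose 43.6-fold, from 6.6 ± 0.561 to 287 ± 24.3 CPM, and the simple-epithelial keratin gene KRT7 rose 3.44-fold. SOX9 (-2.50) and PROM1 (-0.62) fell. Of 18 epithelial junction and keratin genes, 12 rose and 3 fell (median 0.39; camera adjusted p = 0.00895, and 0.0423 with an estimated correlation). The epithelial transcription factor gene ELF3 was 16.4-fold and CDH1, which encodes E-cadherin, 2.71-fold higher, while the keratin gene KRT18 (-0.86) fell. Of 20 interferon-stimulated genes, 15 rose and 2 fell (median 1.2; camera adjusted p = 7.51e-05), IFIT2 by 4.14-fold and IFI27 by 4.96-fold. Of 16 MHC class I antigen presentation genes, 15 rose (median 0.49; camera adjusted p = 0.00612, and 0.0423 with an estimated correlation). TAPBP, the gene of the peptide-loading protein tapasin, rose by 2.31-fold, while TAP2, a subunit of the peptide transporter, fell 2.27-fold. HLA genes are near-identical in places and the counting left out reads with several positions, so their levels are uncertain. Of 26 lysosome and autophagy genes, 19 rose and 3 fell (median 0.48; camera adjusted p = 1.34e-07), with the autophagy genes GABARAPL1 8.29-fold and WIPI1 6.16-fold higher. The integrated stress response and amino acid supply list fell, with 14 of 22 genes lower and 5 higher (median -0.72; camera adjusted p = 0.00167, and 0.0458 with an estimated correlation). The serine synthesis enzyme gene PHGDH and the mitochondrial folate enzyme gene MTHFD2 were 3.60-fold and 3.48-fold lower.

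Further lists passed the test in HuCCT-1 only with the preset correlation. Of 27 cholesterol and fatty acid synthesis genes, 17 rose and 3 fell (median 0.57; camera adjusted p = 0.00127, but adjusted p = 0.123 with an estimated correlation), with HMGCS1, an enzyme of the mevalonate pathway, 3.95-fold higher and TM7SF2 5.72-fold higher. Of 15 mesenchymal genes and EMT factors, 9 rose and 5 fell (median 0.45; camera adjusted p = 0.00373, but adjusted p = 0.0504 with an estimated correlation). FN1, which encodes fibronectin, rose 5.20-fold and SERPINE1, the plasminogen activator inhibitor gene, 3.35-fold, whereas VIM (-0.45), ZEB1 (-1.15) and SNAI1 (-1.65) fell. Of 16 NRF2 targets, 8 rose and 5 fell (median 0.43; camera adjusted p = 0.0419, but adjusted p = 0.0887 with an estimated correlation). AKR1C1 rose 7.73-fold, though it shares sequence with AKR1C2, and the heme oxygenase gene HMOX1 rose 5-fold. The call of this list was also lost without untreated library 3 (adjusted p = 0.0578), without a filter on low counts (0.0533), with the line fitted by itself (0.0601) and with the replicate number as a block (0.17), within a range of 0.0308 to 0.17 over all alternatives with camera (fry, which tests against no change: 2.84e-09). Of the 13 mitochondrially encoded genes, a sign of RNA quality, 12 rose and MT-ND6 fell (median 0.68; camera adjusted p = 0.00965, but adjusted p = 0.542 with an estimated correlation), and their share of all fragments went from 2.83% to 3.11% in untreated to 4.81% to 5.08% in treated libraries. MT-ND5 rose 2.52-fold and MT-CO2 2.02-fold.

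The other lists did not pass the test in HuCCT-1 (camera adjusted p = 0.0613 to 0.971). Members higher and lower were 9 and 8 of 21 RAS proteins, regulators and kinases, 7 and 5 of 14 receptor tyrosine kinases and insulin receptor substrates, 3 and 3 of 6 EGF receptor family ligands, and 5 and 7 of 14 BCL2 family genes. They were 5 and 1 of 7 MHC class II genes, 4 and 8 of 18 NF-kB targets, chemokines and cytokines, 11 and 8 of 20 YAP/TEAD targets, and 10 and 5 of 20 glycolysis genes. Among 6 mucins and trefoil factors 2 were higher and 1 lower, and among 8 WNT feedback targets 2 were higher and 3 lower. Of the lists for other cell types, 3 of 6 tested stromal, endothelial and leukocyte genes were higher and none lower (adjusted p = 0.0613), and 1 of 2 tested hepatocyte genes, SERPINA1, was higher. Median and mean differed in sign for the RAS list (-0.03 and 0.30), the BCL2 family (-0.13 and 0.07) and the WNT targets (-0.40 and 0.14). With p-values adjusted over the list alone, the counts of all 28 lists were as over all genes, in this line and in KKU-213A.

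Among genes past the threshold with a mean log2 CPM of at least 3 over the 6 libraries of the line, no overlap between treated and control libraries and a symbol that is not a clone or locus name, the 6 largest rises in HuCCT-1 were in CD24, ALPP, CEMIP, AHNAK2, TRIM29 and LGALS9. Genes with larger log2 rises than CD24 (5.45) that these limits left out included KRT17 (6.90) and LOXL4 (5.47). CEMIP (ENSG00000103888.17, chromosome 15, 80779343 to 80951776), which encodes a hyaluronan-degrading protein, rose 29.0-fold, from 33.9 ± 0.351 to 984 ± 48.0 CPM. The placental alkaline phosphatase gene ALPP rose 36.6-fold, but near-identical copies make its level uncertain. AHNAK2 rose 24.8-fold, TRIM29 23.7-fold and LGALS9, which encodes galectin-9, 22.7-fold. Under the same limits, which left out DUSP6, the 6 largest falls were in ETV5, SPRY4, ETV4, MYEOV (40.8-fold), the long non-coding RNA gene CASC19 (40.5-fold) and G0S2 (34.6-fold), whose product inhibits the lipase ATGL.

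In treated KKU-213A, ERK-induced transcripts and DNA replication, mitosis and ribosome biogenesis transcripts fell. So did 4 of 6 tested genes of the mucin and trefoil factor list, though the mucin genes MUC1 and MUC16 rose. Transcripts of CDK inhibitors, interferon responses, MHC class I antigen presentation, epithelial junctions, cholangiocytes, cholesterol synthesis, lysosomes and NRF2 targets rose. DUSP6 fell from 186 ± 14.8 to 0.444 ± 0.178 CPM (SD, n = 3 per group), which is 409-fold, and CCND1 fell 16.5-fold, from 321 ± 14.8 to 19.4 ± 3.05 CPM. MYC fell 2.24-fold, from 421 ± 2.22 to 188 ± 12 CPM, and MKI67 fell 6.41-fold, from 623 ± 55.2 to 97.1 ± 5.81 CPM. By edgeR's quasi-likelihood test, 6291 genes were higher and 5106 lower in treated cells at an adjusted p under 0.05, and 2793 and 1863 of these changed at least 2-fold.

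Among the fixed genes, SPRY4 (-4.58, SE 0.15), ETV4 (-5.24, SE 0.11) and ETV5 (-7.67, SE 0.19) fell in KKU-213A, with adjusted p-values of at most 1.34e-18 (edgeR). KRAS rose 2.37-fold, from 97.2 ± 3.86 to 230 ± 33.3 CPM (adjusted p = 1.00e-12), NRAS rose 1.24-fold and CDKN1B 1.32-fold. HRAS (-0.04, adjusted p = 0.516) did not pass the test, and neither did PPIA (-0.05, adjusted p = 0.299). PPIA passed it as lower with KKU-213A fitted by itself (-0.13) or without treated library 3 (-0.10), within a range of -0.13 to -0.02 over all alternatives.

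Of 11 ERK feedback regulators, 9 fell and 2 rose in KKU-213A (median -2.96; camera adjusted p = 9.54e-14), DUSP4 by 32.4-fold. Of 18 other ERK targets, 13 fell and 3 rose (median -2.45; camera adjusted p = 5.07e-14), with FOSL1 20.2-fold and the early response gene IER3 11.5-fold lower. Of 6 EGF receptor family ligands, 4 fell and 1 rose (median -0.85; camera adjusted p = 0.0117, but adjusted p = 0.102 with an estimated correlation), TGFA by 3.27-fold and AREG by 2.18-fold. All 26 G1/S and DNA replication genes (median -2.92; camera adjusted p = 5.69e-60), all 23 G2/M and mitosis genes (median -2.64; camera adjusted p = 4.37e-57) and all 25 ribosome biogenesis genes (median -1.29; camera adjusted p = 1.33e-20) fell. With an estimated correlation, camera's adjusted p-values of these lists were 2.16e-05, 0.000529 and 0.0125. The replication licensing gene CDC6 was 16.2-fold, FEN1 7.86-fold, CDC20 8.37-fold, CCNB1 6.22-fold, ODC1 7.41-fold and LYAR 6.04-fold lower. Of 19 CDK inhibitors and cell cycle exit genes, 15 rose and 1, CDKN2C, fell (median 1.17; camera adjusted p = 2.08e-07), with CDKN2B 17.9-fold and CDKN1A, which encodes p21, 5.11-fold higher. Of 6 mucins and trefoil factors, 4 fell and 1 rose (median -3.56; camera adjusted p = 0.00158, and 0.0471 with an estimated correlation). The intestinal mucin gene MUC2 was 20.4-fold and SPDEF, a transcription factor of goblet cells, 42.9-fold lower, while MUC16 (2.48) was higher.

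Interferon-stimulated genes rose in KKU-213A, with 18 of 20 higher and none lower (median 1.06; camera adjusted p = 9.53e-07), STAT2 by 4.98-fold. MHC class I antigen presentation followed with 15 of 16 higher (median 0.77; camera adjusted p = 9.44e-06), TAPBP by 2.80-fold and HLA-E by 2.38-fold, and TAP2 (-0.29) lower. Of 27 cholesterol and fatty acid synthesis genes, 25 rose and 1, ELOVL6, fell (median 1.25; camera adjusted p = 4.32e-14), with HMGCS1 4.36-fold and LSS, which encodes lanosterol synthase, 4.51-fold higher. Of 26 lysosome and autophagy genes, 22 rose and 2 fell (median 0.72; camera adjusted p = 1.94e-11), PSAP, the saposin precursor gene, by 4.62-fold and the cathepsin D gene CTSD by 3.91-fold. Of 16 NRF2 targets, 11 rose and 1, SRXN1, fell (median 0.69; camera adjusted p = 1.04e-05), with HMOX1 22.3-fold higher and AKR1C2 9.5-fold higher, the latter uncertain because of its paralogs. Of 14 cholangiocyte genes, 11 rose and 2 fell (median 1.68, or 1.5 with genes at 0 at their bound; camera adjusted p = 0.00372), the membrane mucin gene MUC1 by 58.9-fold and CD24 by 5.83-fold. Of 18 epithelial junction and keratin genes, 13 rose and 3 fell (median 0.83; camera adjusted p = 0.00190). ELF3 was 8.01-fold higher, while KRT18 (8.96-fold lower) and its partner keratin gene KRT8 (-0.62) fell.

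Of 6 tested stromal, endothelial and leukocyte genes, 4 rose and 1 fell in KKU-213A (median 2.05; camera adjusted p = 0.0373, but adjusted p = 0.0846 with an estimated correlation). VWF, the von Willebrand factor gene of endothelium and platelets, rose 53.0-fold, from 0.883 ± 0.123 to 47 ± 1.14 CPM, and the collagen gene COL1A1 rose 3.99-fold. It is not known whether reads of a host were removed before counting, which leaves these values uncertain. LUM and CDH5 rose too, and the smooth muscle actin gene ACTA2 (-1.09) fell. The call was lost without treated library 2 (adjusted p = 0.0638) or 3 (0.0644) without a filter on low counts (0.0975) and with the replicate block (0.107), within a range of 0.0128 to 0.107 over all alternatives with camera (fry, which tests against no change: 5.26e-09). The mitochondrially encoded list held 10 higher and 1 lower of 13 genes (median 0.53; camera adjusted p = 0.173), and its share of fragments went from 2.95% to 3.70% in untreated to 4.07% to 5.08% in treated libraries. This list passed without a filter on low counts (camera adjusted p = 0.00489) and with the replicate block (0.0328).

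The remaining lists did not pass the test in KKU-213A (camera adjusted p = 0.0804 to 0.83). Members higher and lower were 14 and 3 of 21 in the RAS list, 6 and 5 of 14 receptor tyrosine kinases and insulin receptor substrates, 9 and 4 of 14 BCL2 family genes, and 5 and 0 of 7 MHC class II genes. They were 10 and 7 of 18 NF-kB targets, chemokines and cytokines, 8 and 9 of 20 YAP/TEAD targets, 7 and 5 of 15 mesenchymal genes and EMT factors, 7 and 6 of 20 glycolysis genes, 11 and 7 of 22 integrated stress response genes, and 1 and 6 of 8 WNT feedback targets. SERPINA1 was again the 1 hepatocyte gene of 2 that was higher. The YAP/TEAD list had a median of -0.04 and a mean of 0.03. Without a filter on low counts the RAS list (camera adjusted p = 0.00489), MHC class II genes (0.00324) and WNT feedback targets (0.016) passed. With the replicate block the RAS list (0.04) and WNT feedback targets (0.0346) did.

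**Figure D2:**
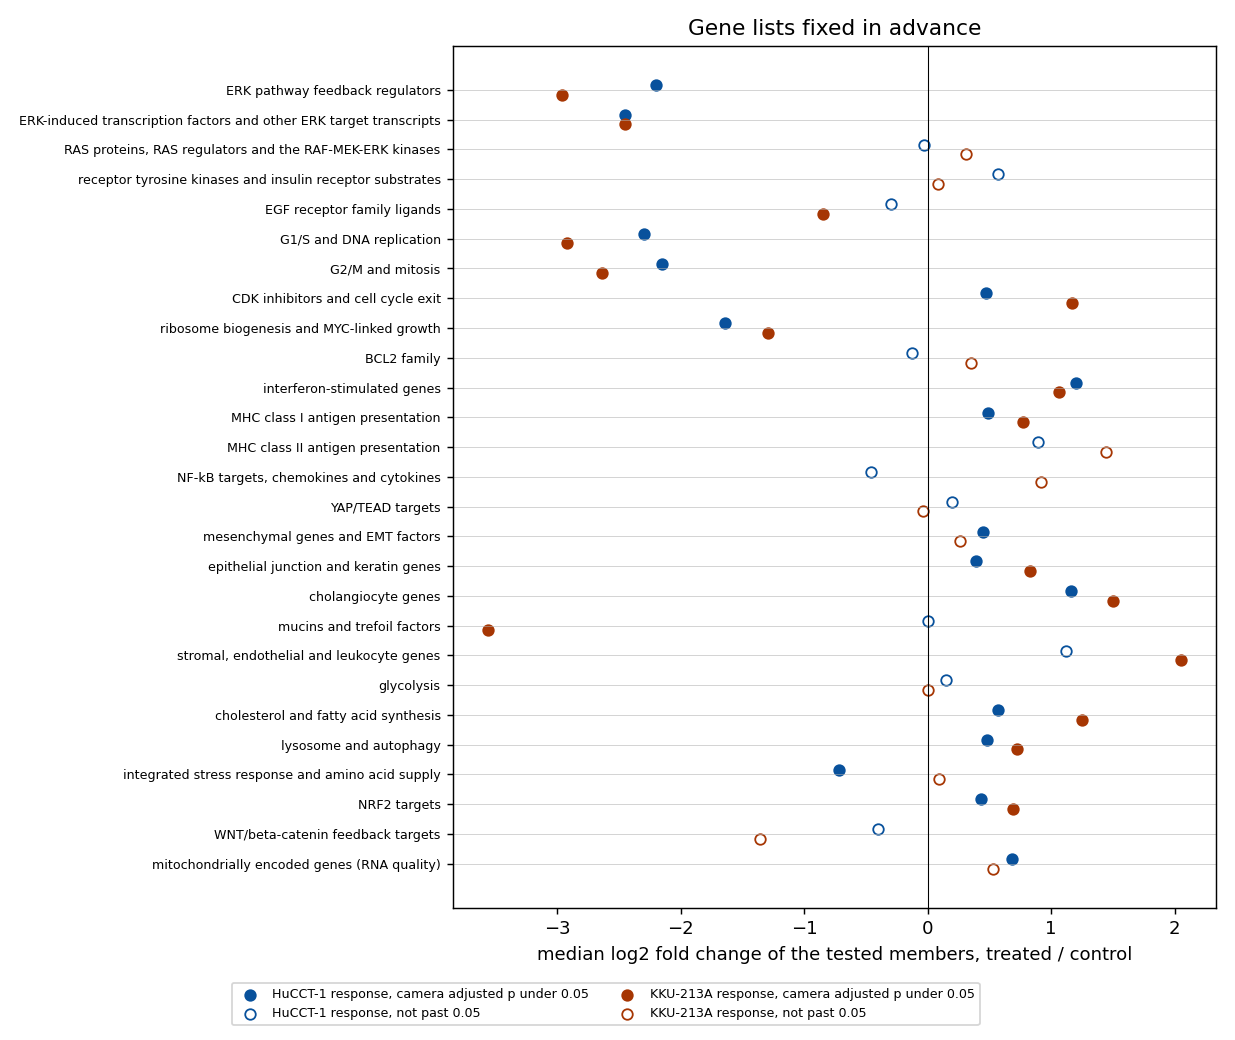
Median log2 fold change, treated over control, of the tested members of 27 gene lists in HuCCT-1 (blue) and KKU-213A (brown); members at 0 in a group are set at their bound, and filled points mark lists with a camera adjusted p under 0.05. The ERK, cell cycle and ribosome biogenesis lists lie at -1.29 or below in both lines.

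Under the same limits, which left out MUC1 and VWF, the 6 largest rises in KKU-213A were in MMP13, which encodes collagenase 3 (ENSG00000137745.13, chromosome 11, 102942995 to 102955732), LOXL4, GNAO1, CXCL10, DUOX2 and C1S. MMP13 rose 141-fold, from 2.75 ± 0.746 to 389 ± 25 CPM, and LOXL4, a lysyl oxidase family gene, 134-fold. The G protein subunit gene GNAO1 rose 88.8-fold, the interferon-inducible chemokine gene CXCL10 60.1-fold, the oxidase gene DUOX2 48.1-fold and the complement gene C1S 42.6-fold. The 6 largest falls under these limits, which left out ETV5, SPDEF and SPRY4, were in DUSP6, ETV4, DUSP4, the transporter gene SLCO4A1 (28.3-fold), DTL (23.7-fold), whose product targets the licensing factor CDT1 for degradation, and MCM10 (21.5-fold), a DNA replication factor.

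Both lines shared a large part of the response. Of the 16321 genes, 3922 were higher in both lines, against 2201 expected of independent lists, and 3723 were lower in both, against 1744. Opposite calls were rarer than expected, with 478 genes higher in HuCCT-1 and lower in KKU-213A (1786 expected) and 618 the other way (2149 expected). The odds ratios of the Fisher's exact tests were 7.63 and 13.6 for the same directions and 0.118 and 0.112 for opposite ones. The 2 comparisons share no library. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.572 and Spearman's rho = 0.629, and r moved to 0.282 without a filter on low counts and to 0.716 with each line fitted by itself. Another 2543 genes were called in HuCCT-1 alone, 2656 in KKU-213A alone and 2381 in neither.

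**Figure D3:**
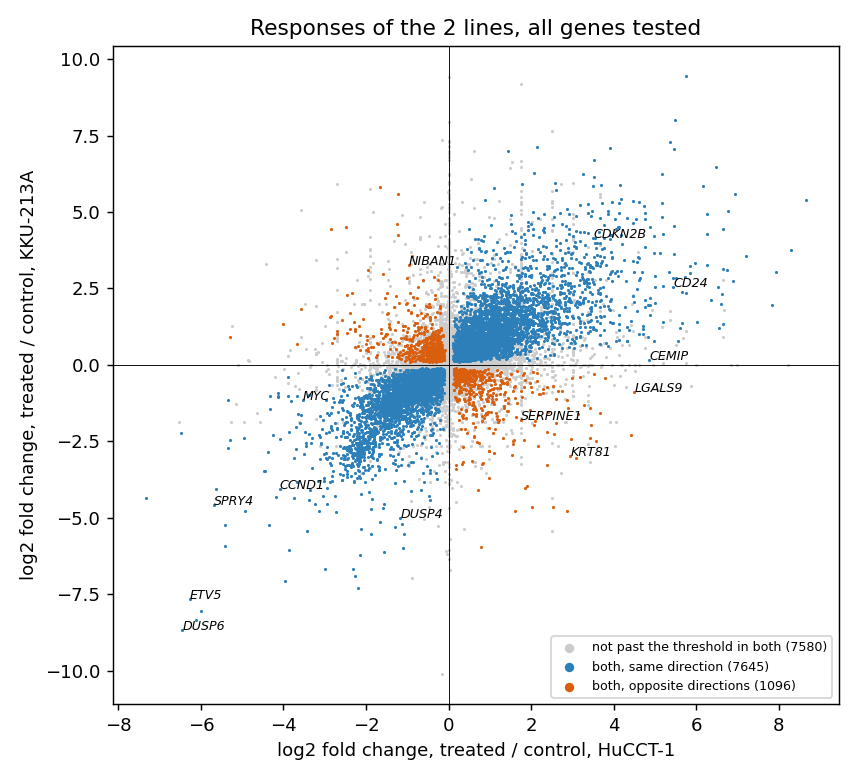
Log2 fold change, treated over control, of each of the 16321 genes tested in HuCCT-1 (x axis) and KKU-213A (y axis). Blue points are the 7645 genes called in the same direction in both lines, orange points the 1096 called in opposite directions and grey points the rest.

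The lines differed in how far, and in places in which direction, genes responded. Amino acid supply transcripts fell in HuCCT-1 and as a list did not pass the test in KKU-213A. Cholesterol synthesis transcripts rose more, and DNA replication transcripts fell further, in KKU-213A than in HuCCT-1. SERPINE1 rose 3.35-fold in HuCCT-1, from 560 ± 8.32 to 1880 ± 62.1 CPM, and fell 3.47-fold in KKU-213A, from 16.9 ± 0.786 to 4.91 ± 0.945 CPM (SD, n = 3 per group). MYC fell by 3.53 on the log2 scale in HuCCT-1 and by 1.16 in KKU-213A. CDKN1A rose by 0.35 in HuCCT-1 and by 2.35 in KKU-213A. The change in KKU-213A minus that in HuCCT-1 was above 0 for 3916 genes and below 0 for 3204 at an adjusted p under 0.05 (edgeR interaction contrast), and 1066 and 1115 of these differed at least 2-fold.

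Among genes past the threshold with a mean log2 CPM of at least 3 over all 12 libraries, which leaves out CXCL10, MMP13 and MUC2, the 5 largest differences towards KKU-213A were in NIBAN1 (4.24, SE 0.10), CASC19 (4.20, SE 0.14), ZNF503 (3.87, SE 0.17), CAMK2N1 (3.81, SE 0.12) and CDC42EP1 (3.74, SE 0.09), on the log2 scale and with edgeR adjusted p-values of at most 2.17e-15. NIBAN1 went from 64.3 ± 2.72 to 33.1 ± 2.20 CPM in HuCCT-1 and from 24.9 ± 2.13 to 241 ± 20.8 CPM in KKU-213A. The 5 largest towards HuCCT-1 were in KRT81 (-5.93, SE 0.23), KRT5 (-5.88, SE 0.88), LGALS9 (-5.38, SE 0.19), CEMIP (-4.70, SE 0.07) and PLXNA2 (-4.51, SE 0.13), with adjusted p-values of at most 8.72e-06. KRT81 (ENSG00000205426.11, chromosome 12, 52285913 to 52291534), a hair keratin gene, rose from 518 ± 7.87 to 4000 ± 19.4 CPM in HuCCT-1, and in KKU-213A it fell from 1.98 ± 0.148 to 0.241 ± 0.106 CPM, which is 108 to 12 reads over the group. KRT81 has close paralogs, so its low level in KKU-213A is uncertain. KRT5 (ENSG00000186081.12, chromosome 12, 52514575 to 52520530) had no read in untreated and 97 reads in treated HuCCT-1, so its difference on the log2 scale is a fitted value only. It ranged from -6.02 to -3.8 over the alternatives, and that of PLXNA2 from -4.57 to -4.47, so the place of KRT5 among these genes is uncertain.

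**Figure D4:**
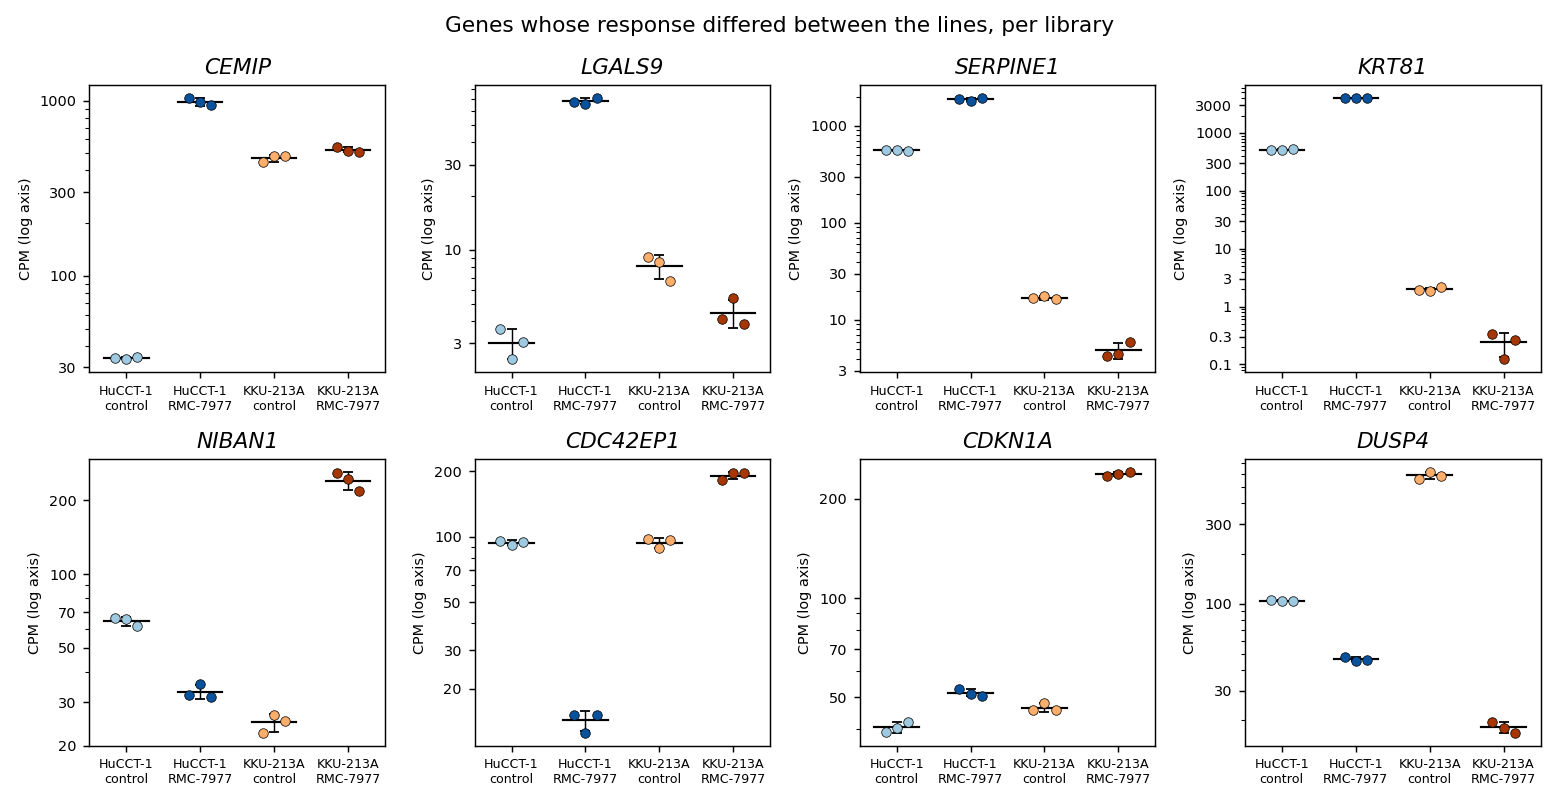
Level of 8 genes whose response differed between the lines, in each of the 12 libraries, in CPM on log axes. Points are libraries, long lines are group means and error bars are SDs (n = 3); SERPINE1, KRT81 and LGALS9 rise in HuCCT-1 and fall in KKU-213A, and NIBAN1 and CDC42EP1 do the reverse.

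Of 27 lists, 12 differed between the lines (camera adjusted p under 0.05). At least as many came from 44 of 100 splits of the libraries, the real one included. Such splits still carry treatment effects, so they do not settle whether chance made this count. The calls that held with an estimated correlation were those of integrated stress response and amino acid supply, cholesterol synthesis and G1/S. The first had 16 of 22 genes above 0 and 3 below (median difference 0.85; camera adjusted p = 1.27e-08, and 0.0174 with an estimated correlation). Its members included the transcription factor gene ATF4 (1.14) and the transporter genes SLC7A11 (2.16) and SLC3A2 (1.44). Cholesterol and fatty acid synthesis had 24 of 27 above and 1 below (median 0.68; camera adjusted p = 1.15e-10, and 0.0496 with an estimated correlation), with LDLR (1.23) and INSIG1 (1.37) among them. G1/S and DNA replication had 19 of 26 below and 2 above (median -0.51; camera adjusted p = 0.000102, and 0.0174 with an estimated correlation), and 20 below adjusted over the list alone.

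The calls of 9 further lists were lost with an estimated correlation. G2/M and mitosis had 21 of 23 genes below 0 (median -0.60; adjusted p = 1.59e-07, then 0.0893 with an estimated correlation) and EGF receptor family ligands 4 of 6 (median -0.62; 0.00171, then 0.084). CDK inhibitors had 8 of 19 above and 1 below (median 0.34; 0.0166, then 0.176, and 0.0552 with the replicate block, within 0.006 to 0.176 over all alternatives with camera), ribosome biogenesis 17 of 25 above and 3 below (median 0.36; 0.00558, then 0.399) and MHC class I 12 of 16 above (median 0.32; 0.0166, then 0.084). NF-kB targets, chemokines and cytokines had 10 of 18 above and 3 below, or 11 and 3 adjusted over the list alone (median 0.95; 0.0163, then 0.084). The neutrophil chemokine genes CXCL8 (2.78) and CXCL1 (2.97) were among those above. Cholangiocyte genes had 7 of 14 below and 3 above, or 7 and 4 adjusted over the list alone (median -0.20; 0.0203, then 0.084, and 0.0664 with the replicate block, within 0.0183 to 0.084 over the same), and NRF2 targets 7 of 16 above and 1 below, or 8 and 2 adjusted over the list alone (median 0.32; 0.0261, then 0.086). Lysosome and autophagy had 14 of 26 above and 4 below (median 0.21; 0.0318, then 0.348), and this call was also lost with DESeq2's size factors (adjusted p = 0.0781, within a range of 0.00152 to 0.348 over all alternatives with camera; fry, which tests against no change: 6.84e-06). The other 15 lists had adjusted p-values from 0.0768 to 0.895. Median and mean differed in sign for ERK feedback regulators (0.45 and -0.19), receptor tyrosine kinases (0.17 and -0.13), MHC class II genes (-0.25 and 0.62) and mesenchymal genes (0.14 and -0.02), and the test for the epithelial list pointed down against a median of 0.12.

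Before treatment, KRT5, KRT17 and TP63 were among the genes higher in KKU-213A, and COL8A1 and VEGFC among those higher in HuCCT-1. Of 27 lists, 2 passed camera's test, mucins and mesenchymal genes, and both calls were lost with an estimated correlation. KRT5, the main type II keratin gene of basal epithelium, stood at 2480 ± 107 CPM in untreated KKU-213A (SD, n = 3) and had no read in untreated HuCCT-1, at least 43700-fold higher against a floor of 3 reads over the group. KRT17 stood at 2570 ± 25.2 against 0.257 ± 0.0693 CPM, and TP63, the gene of the basal transcription factor p63, at 303 ± 8.41 against 0.164 ± 0.0677 CPM. The aldehyde dehydrogenase gene ALDH3A1 (679 ± 17.2 against 0.0816 ± 0.0516 CPM) and LY6D (189 ± 20.3 against 0.271 ± 0.203 CPM) were also higher in KKU-213A. Higher in HuCCT-1 were the collagen gene COL8A1 (465-fold), JCAD (324-fold), the endothelial phosphatase gene PTPRB (298-fold), the growth factor gene VEGFC (264-fold) and KRT81 (261-fold). By edgeR's test 6266 genes were higher and 6447 lower in KKU-213A at an adjusted p under 0.05, 3120 and 2909 of them at least 2-fold.

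Of 6 mucins and trefoil factors, 5 were higher and 1 lower in KKU-213A (median 6.42, or 4.90 with genes at 0 at their bound; camera adjusted p = 6.64e-05, but adjusted p = 0.0504 with an estimated correlation). MUC2 had 4208 reads in untreated KKU-213A and none in untreated HuCCT-1. Of 15 mesenchymal genes and EMT factors, 9 were lower and 5 higher (median -1.01; camera adjusted p = 0.00905, but adjusted p = 0.171 with an estimated correlation), SERPINE1 by 33.0-fold and FN1 by 46.2-fold. The latter call was also lost without a filter on low counts (adjusted p = 0.188) and with the replicate block (0.227), within a range of 0.00169 to 0.227 over all alternatives with camera (fry, which tests against no change: 5.02e-10). Both tested hepatocyte genes were lower in KKU-213A. The other 25 lists had adjusted p-values from 0.0917 to 0.978, and 6 of them had a median and a mean or test of different sign.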

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

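The split with swapped labels, the tests of keratin reads, of a common factor for mitochondrial transcripts, and of scaling and matched random lists were chosen after the results were seen; the other splits of the libraries and the test of MALAT1 and NEAT1 were chosen earlier.

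Of 84 named genes, 69 responded differently in the 2 lines by the interaction test, and so did 12 lists. The named genes include those picked for the largest differences past this test, and others picked as extreme in 1 line. Their count was therefore partly fixed in advance. Over all 16321 genes tested, 43.6% passed the interaction test. Values below are log2 differences, KKU-213A minus HuCCT-1. Groups of 3 libraries were too small for a test of single outlying libraries.

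The lines moved in opposite directions, each past the threshold, for 10 of these genes. Among them LGALS9, KRT81, PLXNA2, NIBAN1, ZNF503, CAMK2N1 and CDC42EP1 had been picked for a large difference between the lines. The changes in HuCCT-1 and KKU-213A were 4.50 and -0.88 for LGALS9 (difference -5.38), 1.74 and -1.80 for SERPINE1 (-3.54), 2.38 and -0.72 for FN1 (-3.10), 0.18 and -1.12 for AREG (-1.31), and 2.95 and -2.98 for KRT81 (-5.93). They were 2.61 and -1.89 for PLXNA2 (-4.51), -0.96 and 3.28 for NIBAN1 (4.24), -1.02 and 2.85 for ZNF503 (3.87), -2.71 and 1.10 for CAMK2N1 (3.81), and -2.71 and 1.02 for CDC42EP1 (3.74).

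Among RAS pathway genes the differences were 0.32 for KRAS, 0.33 for HRAS, 0.28 for PPIA, -2.23 for DUSP6, 1.10 for SPRY4, -1.40 for ETV5, 2.36 for MYC, -3.85 for DUSP4, -3.23 for IER3 and -0.86 for TGFA. Over the treated groups of HuCCT-1 and KKU-213A, DUSP6 had 39 and 22 reads, SPRY4 89 and 44, and ETV5 55 and 8. The differences of these genes therefore rest on few reads in treated cells. For the cell cycle and growth they were -0.48 for MKI67, -0.43 for MCM2, -0.48 for FEN1, -0.22 for CCNB1, -0.53 for CDC20, -1.33 for DTL, -1.05 for MCM10, -1.07 for CDC6, 0.66 for CDKN2B, 2.01 for CDKN1A, -0.66 for ODC1, 0.48 for NOP56 and 0.49 for LYAR. Immune genes gave -1.28 for IFIT2, 0.27 for TAPBP, 0.89 for TAP2, 0.74 for STAT2, 0.50 for HLA-E and 1.22 for C1S. Epithelial genes gave -2.90 for CD24, -1.03 for ELF3, -1.30 for KRT7, -2.30 for KRT18, 2.19 for MUC1, -1.98 for SPDEF and -2.10 for TRIM29.

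Metabolic and stress genes gave -0.47 for GABARAPL1, 0.52 for WIPI1, 1.21 for PSAP, 1.02 for CTSD, 1.00 for MTHFD2, 1.34 for PHGDH, 1.09 for LSS, 2.16 for HMOX1, 0.82 for AKR1C2 and -0.31 for MT-CO2. The others were -4.70 for CEMIP, -1.79 for AHNAK2, -2.63 for ALPP, 2.62 for MYEOV, 4.20 for CASC19, 1.6 for LOXL4, 5 for MMP13, 3.13 for VWF, 0.58 for COL1A1 and -2.08 for SLCO4A1. For CXCL10 (8.61), MUC2 (-6.87) and KRT5 (-5.88), HuCCT-1 had 2 and 0, 0 and 2, and 0 and 97 reads in untreated and treated cells, so these are fitted values only. MMP13 had 4 and 22 reads there. ALPP had 7 and 39 reads in untreated and treated KKU-213A.

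The median differences of the 12 lists were -0.62 for EGF receptor family ligands, -0.51 for G1/S, -0.60 for G2/M, 0.34 for CDK inhibitors, 0.36 for ribosome biogenesis, 0.32 for MHC class I, 0.95 for NF-kB targets, -0.20 for cholangiocyte genes, 0.68 for cholesterol synthesis, 0.21 for lysosome, 0.85 for integrated stress response and 0.32 for NRF2 targets.

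Of 100 of the 200 possible splits of the libraries within the lines, 1, the real one, gave as many genes that differed (7120; highest other 4593). That other count came from the 24 splits that kept the treated and control libraries of one line apart, and edgeR called 0 genes in the splits that mixed both lines. Mixed splits carry the treatment effect in their spread. The split that swaps the labels of KKU-213A was not among those drawn and, fitted by itself after the results were seen, gave 11869 genes and 14 lists, which reflects the response that the lines share. These splits therefore do not settle whether chance made the count of genes. For lists, 44 of the 100 gave at least 12 (highest other 17). Splits that mixed both lines gave up to 14 lists though 0 genes, so the splits cannot settle the count of lists either. For genes called in the same direction in both lines, 1 of 100 gave as many (7645; highest other 0 by edgeR). The splits do not settle this, because mixed splits carry the treatment effect in their spread. The counts above those expected of independent lists (3922 against 2201 higher, 3723 against 1744 lower) argue against a chance overlap of the 2 sets of calls, though genes are not independent. Within a line there are only 10 splits of 6 libraries, too few for a share under 0.05. The real split was the 1 with the most genes in HuCCT-1 (11284; highest other 0 by edgeR), KKU-213A (11397; 0) and the untreated lines (12713; 0), and with the most lists (16, 16 and 2; highest others 11, 14 and 1).

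Treated HuCCT-1 held reads of keratin genes that are abundant in KKU-213A, 1999 of KRT17, 97 of KRT5, 41 of KRT6A, 25 of KRT16, 15 of KRT13, 1 of KRT4 and 0 of KRT14, where untreated HuCCT-1 had 14 of KRT17, 4 of KRT16 and none of the others. These 7 have at most 20 reads in untreated HuCCT-1 and at least 1000 in treated KKU-213A. Reads crossing from KKU-213A, into every HuCCT-1 library or into the treated ones alone, would stand in proportion to the reads in treated KKU-213A, and they did not (chi-square test on the read counts, heterogeneity p = 2.51e-220; from 0 per 10000 for KRT14 to 23.7 for KRT17), which argues against crossing as the whole cause. For KRT5 alone crossing cannot be told apart from transcription, because 19 other genes had 109 reads with 56.6 expected at its rate, and 8 of them fell below it. Reads of KRT81 counted for its paralogs stay open. The 242 reads expected against 18 found in untreated HuCCT-1 come from genes chosen for few reads there, so they cannot decide. Most of the treated reads were of KRT17, which rose more than KRT81 (log2 fold changes 6.90, SE 0.13, and 2.95, SE 0.04). How alike the sequences of KRT81 and these 7 genes are was not examined. An effect of the treatment stays open as well.

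Mitochondrially encoded transcripts took a larger share in the treated libraries of both lines. A single factor common to all of them is argued against as the whole cause, because their changes differed by more than their errors (larger heterogeneity p of the 2 lines 8.61e-57). The test cannot exclude a common factor with further changes of single genes. Loss of cytoplasmic RNA from damaged cells stays open, because the nuclear transcripts MALAT1 and NEAT1 rose too (lowest log2 fold change 0.88). An effect of the treatment on mitochondrial transcripts could be an alternative and also stays open.

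The responses of the integrated stress response and cholesterol synthesis lists differed between the lines. The first list fell in HuCCT-1 (median -0.72) and did not pass the test in KKU-213A (median 0.09). The second had medians of 0.57 in HuCCT-1 and 1.25 in KKU-213A. Expression level and gene length of the members are argued against, because both median differences were at percentile 100 of 10000 matched random lists, whose central 95% spanned -0.20 to 0.31 and -0.11 to 0.28. Scaling of the libraries was checked with DESeq2's size factors. They changed the calls of 1050 single genes in the difference, but moved the median difference of all genes only from 0.056 to -0.006. A shift of this size could not have taken the median differences of these lists to 0, so the check cannot decide about scaling. With these size factors the median differences went from 0.85 (SE 0.19) to 0.79 (SE 0.19) and from 0.68 (SE 0.11) to 0.61 (SE 0.11), 4.2 and 5.3 standard errors from 0. These SEs come from resampling the member genes of each list, so they do not measure the spread between libraries. Both lists stayed past the threshold (camera adjusted p = 2.22e-08 and 7.48e-10, within ranges of 8.21e-11 to 0.0174 and 5.7e-17 to 0.0496 over all alternatives). A change in the total RNA per cell cannot be seen by either scaling. It stays open, as does a difference between the lines, and each line stands for itself only.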

How the results depend on the processing

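All alternatives were chosen before any result was seen; the cause of the changes below was not tested unless stated.

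The counts of genes kept within 1.5 times their values under every alternative run for them. Over the alternatives that keep all libraries they ranged from 10853 to 11577 in HuCCT-1, 10905 to 11927 in KKU-213A, 6809 to 7484 for the difference and 12019 to 13609 for the untreated lines. Without 1 library they ranged from 10737 to 11561, 11023 to 11682, 6536 to 7254 and 12325 to 13024. Named genes were checked only in the comparison that named them, where they kept their direction and side of the threshold with 2 exceptions. PPIA in KKU-213A passed with the line by itself (-0.13) or without KKU-213A treated 3 (-0.10). NRAS in HuCCT-1 ranged from -0.05 (without HuCCT-1 treated 2) to 0.14. Most of the differences between the lines given above for 69 named genes were therefore not checked under the alternatives. In that contrast DESeq2's size factors changed the calls of 1050 single genes. DESeq2's size factors moved the share of called genes that were higher from 50.6% to 54.3% in HuCCT-1 and from 55% to 47.6% for the difference.

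Without a filter, 6 lists passed for the untreated lines, and signs turned for BCL2 in HuCCT-1 (adjusted p = 0.57), YAP in KKU-213A (0.467), epithelial genes in the difference (0.485) and, for the untreated lines, ERK targets (0.788), RAS (0.584), NF-kB (0.702), lysosome (0.846) and WNT (0.702). With the stricter filter WNT in HuCCT-1 turned (0.987). With each line by itself BCL2 in HuCCT-1 (0.96), glycolysis in KKU-213A (0.97) and ribosome biogenesis in the untreated lines (0.995) turned. With the replicate block 1 list passed for the untreated lines, and signs turned for BCL2 in HuCCT-1 (0.792), YAP (0.577) and glycolysis (0.991) in KKU-213A, epithelial genes in the difference (0.591) and, for the untreated lines, ERK targets (0.899), RAS (0.897), NF-kB (0.86), lysosome (0.899) and WNT (0.899). With fry BCL2 in HuCCT-1 (0.646) and epithelial genes in the difference (0.773) turned. None of these lists was past the threshold as reported.

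With an estimated correlation, 11 lists passed in HuCCT-1, 14 in KKU-213A, 3 for the difference and 0 (camera; fry 21) for the untreated lines. Camera's adjusted p-values of the passing lists then ranged from 6.22e-06 to 0.0458 in HuCCT-1 and from 2.16e-05 to 0.0471 in KKU-213A. With fry, which tests each list by itself and not against other genes, 25, 27, 24 and 21 passed.

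Among list results, 107 kept their direction and side of the threshold with DESeq2's size factors (1 lost its call), 83 without a filter (3 lost, 14 gained), 106 with the stricter filter (1 gained), 90 with the replicate block (5 lost, 4 gained), 90 with an estimated correlation (18 lost) and 55 with fry (51 gained). With each line by itself, which leaves out the difference, 77 did (1 lost, 3 changed sign). Over all fits without 1 library 1259 did (3 lost, 9 gained, 25 changed sign).

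The correlation of the responses (r = 0.572) was 0.282 without a filter, 0.6 with the stricter filter and 0.716 with each line by itself. It ranged from 0.553 to 0.56 without 1 library.

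Without 1 library, adjusted p ranged, for lists whose sign turned, from 0.929 to 0.988 (BCL2, HuCCT-1), 0.336 to 0.848 (YAP, KKU-213A), 0.71 to 0.995 (epithelial, difference) and, for the untreated lines, 0.851 to 0.993 (receptor tyrosine kinases), 0.851 to 0.984 (NF-kB) and 0.925 to 0.993 (lysosome). Calls ended for NRF2 targets in HuCCT-1 without HuCCT-1 control 3 (0.0578) and for stromal genes in KKU-213A without KKU-213A treated 2 (0.0638) or 3 (0.0644). Calls appeared for stromal genes in HuCCT-1 without HuCCT-1 treated 2 (0.0465), RAS in KKU-213A without KKU-213A treated 3 (0.0367), mitochondrial genes in KKU-213A without KKU-213A control 1 (0.0478) or treated 2 (0.0221) and in the difference without control 3 (0.045) or treated 3 (0.0183), and YAP in the untreated lines without HuCCT-1 control 1 (0.0493) or 3 (0.0428) or KKU-213A treated 3 (0.0418).

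Not run were each line by itself for the difference, which needs both lines, and DESeq2 and limma-voom for lists. In the simulation a 2-fold change was recovered for 66% to 86% of the changed genes. Far fewer genes were changed there than were called in the data, so this rate need not hold for the data.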

Other observations

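The grouping of genes by the stem of their symbols was chosen after results were seen.

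Of 92 families with at least 15 tested members, none passed with an estimated correlation. Of 32 keratin genes, 17 rose and 1 fell in HuCCT-1 (camera adjusted p = 0.000474, but 0.132 with an estimated correlation) and 27 rose and 5 fell in KKU-213A (5.36e-09, but 0.0596), with the same counts under DESeq2's size factors. Of 49 RPL genes, pseudogenes left out by their symbols, 0 rose and 43 fell in HuCCT-1 by edgeR (0 and 41 with DESeq2's size factors), 24 rose and 6 fell in KKU-213A (23 and 6), and 45 lay above 0 in the difference (41). Of 25 SNHG genes, 2 rose and 20 fell in HuCCT-1 (2 and 20), 5 rose and 11 fell in KKU-213A (5 and 11; camera adjusted p = 0.444) and 17 lay above 0 in the difference (16). Of 49 MRPL genes, 42 fell in HuCCT-1 (41) and 37 in KKU-213A (37).

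In KKU-213A, KRT4 went from 515 to 15735 reads and KRT1 from 0 to 232 reads over the group. The 10 most abundant genes took 5.80% to 5.92% of fragments in untreated and 8.04% to 8.28% in treated HuCCT-1, and 4.86% to 5.14% and 7.53% to 8.16% in KKU-213A.

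The replicate numbers showed no clear pairing of libraries across treatment, though correlations this low cannot exclude one. Correlations of same-numbered libraries were -0.03, 0.04 and 0.07 in HuCCT-1 and -0.02, 0.02 and 0.04 in KKU-213A, and the highest with other numbers were 0.06, -0.02 and 0.05, and 0.03, 0.01 and 0.01.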
